A study of Mus musculus with 18 samples.

How the data were processed

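Ribosome profiling was performed on E14 mouse embryonic stem cells, WT or with a knockout of Quaking or Sam68, either as stem cells (day 0) or after 10 days as embryoid bodies (day 10). Per the labels' protocols, cells were treated with cycloheximide (100 µg/mL for 15 minutes), which stalls ribosomes, unprotected RNA was digested with a nuclease, ribosomes were collected through a sucrose cushion and fragments of 28 to 32 nt were cut from a gel. Each of the 18 samples had 1 deposited file of raw counts per gene, as whole numbers for 51826 versioned Ensembl IDs in the same order. Per the submitters' processing notes, bcl2fastq 2.17.1.14, Bowtie2 and STAR 2.5.3a were used with the mouse builds mm10 and GRCm38; the counting program, the annotation release and the use of strand are not given in the sources used here. Because strand use is not given, counts of overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain. No matched measurement of mRNA amount was used here, so translational efficiency was not computed.

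Groups and replicate numbers came from the sample labels and pools from the sample descriptions. Total counts ranged from 988210 to 10646768 per library. A floor of 3 counts corresponded to 0.233 CPM in the deepest library and 7.05 CPM in WT day 10 replicate 3, the library with the smallest size after scaling. Floors and counting intervals (95%, exact binomial) cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of replicates agreed within sampling noise (chi-square per degree of freedom at least 5.32), so each library was counted once.

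The main test was edgeR 4.0.16's quasi-likelihood test (R 4.3.3, robust fit) on the deposited counts, with TMM scaling and edgeR's default filter on low counts by group, which kept 13701 of the 33167 genes with any count and at least 99.4% of each library's counts. All 18 libraries entered 1 fit with a mean per group, so that 6 groups of 3 shared an estimate of spread; the common biological coefficient of variation was 0.229. There were 10 comparisons, 2 of them interactions. Genes were called at a Benjamini-Hochberg adjusted p of 0.05, two-sided. CPM are scaled by the TMM library sizes, and errors are SD over 3 libraries. These comparisons, the test and the alternative settings, other than those said to be added, were fixed before the data were examined.

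On simulated counts for the 13701 genes with 50 changed at each of 4 fold sizes, the Quaking KO vs WT day 0 test recovered 30% of 2-fold, 62% of 4-fold and 82% of 8-fold changes, with 7.29% of calls false. For Quaking KO vs WT at day 10 it recovered 34%, 70% and 88%, with 4.81% false, and for Sam68 KO vs WT at day 10 26%, 76% and 90%, with 8.33% false. At 1.5-fold it recovered 4%, 6% and 6%.

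The reference table given for names held 49997 genes of the GRCm38 assembly and no Ensembl ID, so 0 IDs were matched to a symbol. The 27 gene lists fixed by symbol before the data were examined, the check of the knocked-out genes and the protein-coding-only alternative could therefore not be run. The rule for the features named in the text was also fixed: past the threshold, at least 10 CPM in the higher group, and no overlap of replicates between the groups (not required for interactions), ranked by log2 fold change. Without names it was applied to all features, and at most 2 IDs are given per direction and comparison; features with no count in a group get a lower bound in place of a fold.

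Gene groups were chosen after the data had been seen, in place of the lists fixed by symbol. Genes that rose or fell with differentiation were those past the threshold with a log2 fold change of at least 1 between day 0 and day 10 in the other knockout line, so that no library was shared with the knockout vs WT comparison. They do share pools with it: Sam68 KO between the days runs from MIX_2 to MIX_3, as Quaking KO vs WT at day 10 does. Cell-cycle lists were the mouse marker pairs distributed with scran 1.30.0, reduced to genes marking only 1 phase (G1 55, S 100 and G2/M 52 tested). Lists were tested with camera (preset correlation 0.01), with an estimated correlation and with fry, adjusted over 8 differentiation and 30 cell-cycle tests. Fisher's exact tests of the class counts (16 in all) were added after those counts and the camera results had been seen. They do not account for differences in level between the classes.

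The alternative settings were RLE and upper quartile scaling, no filter on low counts, DESeq2 1.42.0, a fit of only the compared groups, a replicate block, pool as a block in an additive model, thinning of every library to 988210 counts, and leaving out each library in turn. Leaving out the 3 libraries in which 10 features took over 40% of the counts was added after the data had been seen. So was the simulation of unchanged groups drawn at the Quaking KO day 10 means. Without those 3 libraries, Sam68 KO at day 10 keeps 1 library, and the spread of that group is not measured. Replicate numbers were checked for pairing by the correlation of deviations from group means.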

Results

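Ribosome-protected fragments, the short pieces of mRNA that a translating ribosome shields from nuclease, were counted per gene in E14 cells, a mouse embryonic stem cell line. Unedited cells (WT) were compared with knockout lines (KO) of the same background lacking Quaking or Sam68, both of which are RNA-binding proteins of the STAR family. Each line was sampled as stem cells at day 0 and at day 10 of embryoid body differentiation, in which stem cells grow as aggregates and form early embryonic cell types. There were 6 groups of 3 libraries, 18 in all, which the series describes as biological triplicates. Total counts per library were 5413775 to 10646768 for WT, 1373377 to 3019843 for Quaking KO and 4629369 to 8062158 for Sam68 KO at day 0. At day 10 they were 1175919 to 6513343 for WT, 988210 to 3281358 for Quaking KO and 2196924 to 7885195 for Sam68 KO. For a translated gene, a count reflects both the amount of its mRNA and how often it is translated, and the footprints alone do not separate them. The features were not limited to protein-coding genes, so some counts may come from RNA that is not translated.

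The files identify features by Ensembl ID and do not pair the IDs with gene names, so features are given by ID and gene groups are those that could be formed from IDs. For the same reason the counts of the genes encoding Quaking and Sam68 were not examined, and the genotypes rest on the labels alone. The libraries were sequenced in 3 pools: MIX_1 held WT and Quaking KO at day 0, MIX_2 held Sam68 KO at day 0 and WT at day 10, and MIX_3 held both knockouts at day 10. Only Quaking KO vs WT at day 0 and Sam68 KO vs Quaking KO at day 10 therefore lie within a pool; in every other comparison pool and group differ together.

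Day of differentiation separated the libraries more than genotype. The first principal component of log2 CPM, counts scaled to a common library size, held 68.3% of the variance and split day 0 from day 10, and the second held 10.0%. Few features took a large share of the counts in some day 10 libraries: the 10 largest took 70.4% in WT replicate 3, 60.2% in Sam68 KO replicate 2 and 64.4% in Sam68 KO replicate 3, against at most 30.2% in the other day 10 libraries. In the day 0 libraries this share was 7.01% to 21.3%. In WT replicate 3 and Sam68 KO replicate 3 the largest were ENSMUSG00000064339.1 (17.9% and 20.9%) and ENSMUSG00000064337.1 (14.6% and 19.01%), and in Sam68 KO replicate 2 it was ENSMUSG00000108010.1 (21.0%). Feature ENSMUSG00000058488.7, the largest in most other libraries, held 1.95% to 23.2% of a library's counts.

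**Figure D1:**
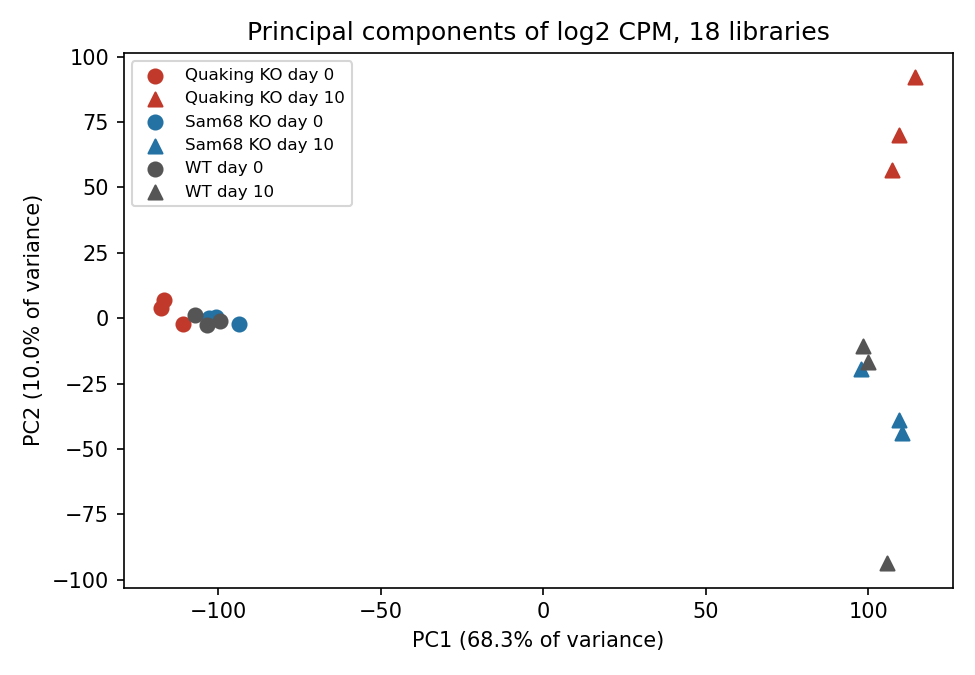
Each point is 1 of the 18 libraries, placed by its first (68.3% of the variance) and second (10.0%) principal component score of log2 CPM, with circles for day 0 and triangles for day 10. Day 0 and day 10 libraries lie apart on the first axis, and the 3 Quaking KO day 10 libraries lie above the other day 10 libraries on the second. WT day 10 replicate 3 lies lowest on the second axis (score -93.7, against -10.6 and -16.7 for its replicates). Its rank correlation was 0.882 and 0.880 with its replicates and 0.910 and 0.913 with Sam68 KO day 10 replicates 2 and 3.

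**Figure D2:**
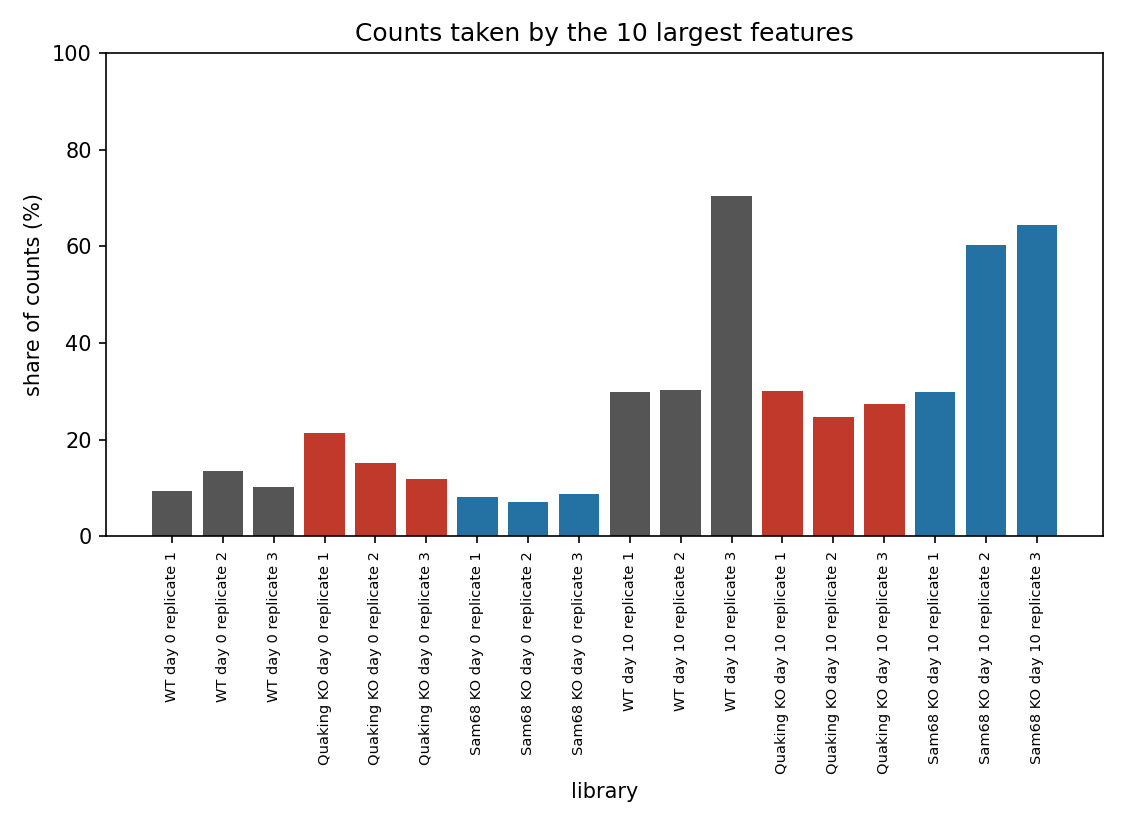
Bars give the percentage of each library's counts held by its 10 largest features. WT day 10 replicate 3 (70.4%) and Sam68 KO day 10 replicates 2 (60.2%) and 3 (64.4%) stand apart from the rest.

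Differentiation changed most of the genes tested in WT cells. Of 13701 genes, 4778 were higher and 4127 lower at day 10 than at day 0 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 3743 and 2699 of them by at least 2-fold. Feature ENSMUSG00000027750.16 had no count in any WT day 0 library and 696 ± 153 CPM (SD, n = 3) at day 10, at least 1919-fold higher against a floor of 3 counts per library. Feature ENSMUSG00000061808.3 rose from 1 count over the WT day 0 libraries to 1375 ± 188 CPM, a ratio of 36541 with a 95% counting interval of 6558 to 1443400. Among those that fell, ENSMUSG00000027702.7 went from 23.5 ± 3.07 CPM to no count, at least 8.65-fold lower, and ENSMUSG00000029205.12 from 21.3 ± 1.87 CPM to no count, at least 7.85-fold lower. Markers of the G2/M phase of the cell cycle fell as a group, with 29 of 52 lower and 8 higher and a median log2 fold change of -0.54 (camera, adjusted p = 0.0157 over 30 tests; adjusted p = 0.299 with an estimated correlation). The S-phase markers had 41 of 100 lower and 18 higher (camera, adjusted p = 0.0507), and the G1 markers 23 of 55 lower and 11 higher (camera, adjusted p = 0.0921); neither group passed the test. The S-phase list passed without WT day 0 replicate 1 (0.0413) and WT day 10 replicates 1 (0.0256) and 2 (0.0242), with RLE (0.0497) or upper quartile scaling (0.0468) and in the fit of only the compared groups (0.0353). Both lists passed with no filter on low counts (3.34e-05 for S and 0.000606 for G1) and by fry, which does not compare a list with other genes (2.72e-05 and 4.13e-05), and neither passed with an estimated correlation (0.469 for each).

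Both knockout lines changed a similar number of genes over the same 10 days. In Quaking KO cells 4755 genes were higher and 4022 lower at day 10, and in Sam68 KO cells 4775 and 4173 (edgeR, adjusted p below 0.05). Across all 3 lines 6526 genes were called in the same direction, 3444 of them higher and 3082 lower at day 10. WT and Quaking KO shared 7123 calls in the same direction, against 2870 for independent lists, and 92 were called in opposite directions. WT and Sam68 KO shared 7722, against 2922, with 12 opposite. Log2 fold changes correlated across genes, which are not independent replicates, with r = 0.860 between WT and Quaking KO and 0.922 between WT and Sam68 KO. These time courses share no library.

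Features named in the knockout time courses went from no or few counts to high levels, or the reverse. In Quaking KO cells ENSMUSG00000048126.16 went from no count to 480 ± 33.1 CPM, at least 406-fold higher (n = 3), and ENSMUSG00000026043.18 from 3 counts to 5137 ± 457 CPM, a ratio of 14036 with a counting interval of 4803 to 68066. In the same cells ENSMUSG00000061928.6 went from 58.6 ± 7.49 CPM to no count, at least 40.0-fold lower, and ENSMUSG00000010342.16 from 33.3 ± 5.95 CPM to no count, at least 22.7-fold lower. In Sam68 KO cells ENSMUSG00000024029.4 went from no count to 72.2 ± 12.3 CPM, at least 171-fold higher, and ENSMUSG00000038624.13 from 1 count to 273 ± 54.1 CPM, a ratio of 6801 with a counting interval of 1220 to 268693. There ENSMUSG00000035557.9 fell from 36.2 ± 6.06 CPM to no count, at least 23.6-fold lower, and ENSMUSG00000029205.12 from 26.0 ± 3.63 CPM to no count, at least 17.0-fold lower. G2/M markers fell in both, with 26 of 52 lower and 9 higher in Quaking KO (median -0.53; camera, adjusted p = 0.0455) and 31 lower and 7 higher in Sam68 KO (median -0.61; adjusted p = 0.0157). Neither call held with an estimated correlation (adjusted p = 0.299 in each), and the Quaking KO call was lost without Quaking KO day 10 replicate 1 (camera, adjusted p = 0.0502) and on thinning all libraries to 1 total (0.0642). The G1 and S lists did not pass in Quaking KO (camera, adjusted p = 0.0538 and 0.0611) or in Sam68 KO (0.181 and 0.0611). In Quaking KO the G1 list passed without day 0 replicate 1 (0.0437) or day 10 replicate 2 (0.0405), with RLE (0.0497) or upper quartile scaling (0.0468), and in the fit of only the compared groups (0.0353). The S list passed there without day 0 replicate 1 (0.0481) and with only the compared groups (0.0497). In Sam68 KO the S list passed without day 0 replicate 3 (0.0472) or day 10 replicate 1 (0.0332) and with only the compared groups (0.0482). With no filter on low counts both lists passed in Quaking KO (0.000141 for G1 and 7.52e-05 for S) and in Sam68 KO (0.00236 and 8.99e-05), as they did by fry (7.18e-07 and 7.65e-05, then 2.17e-05 and 7.27e-05), but none did with an estimated correlation (0.299 and 0.540, then 0.469 and 0.540). With pool as a block in an additive fit, which gives 1 day effect for all lines, 5570 genes were called.

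**Figure D3:**
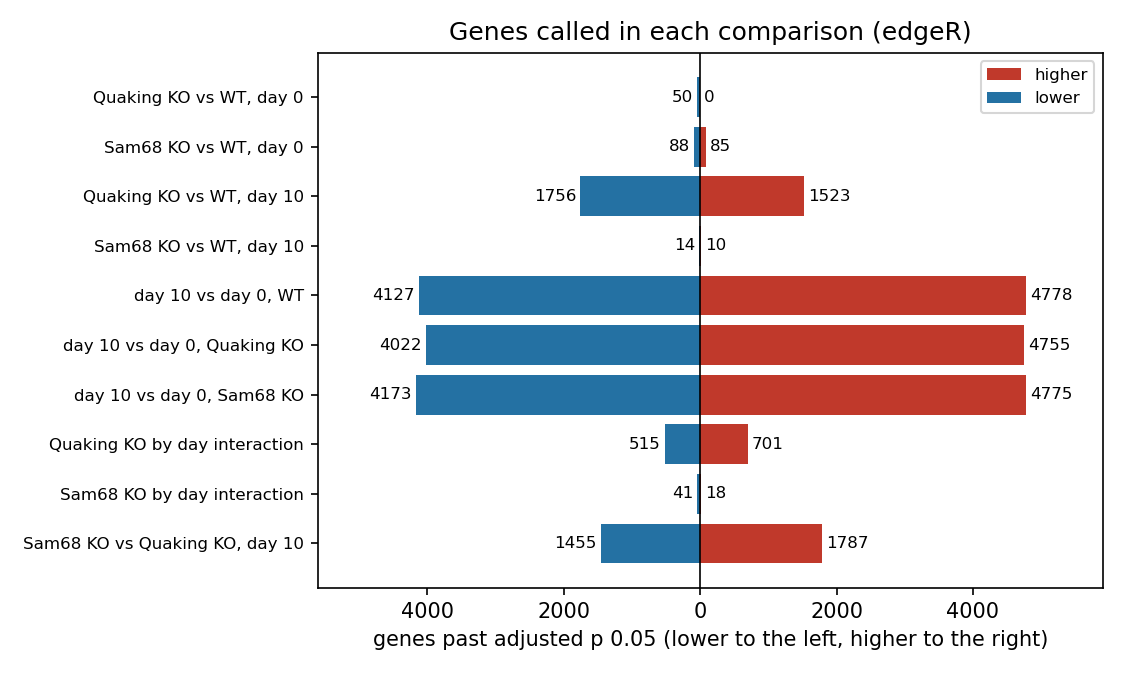
Bars give the number of the 13701 tested genes past an adjusted p of 0.05 in each comparison, higher to the right and lower to the left. The 3 time courses call 8777 to 8948 genes each, Quaking KO vs WT at day 10 calls 3279 and Sam68 KO vs WT at day 10 calls 24.

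Before differentiation, loss of Quaking was accompanied by lower counts of a small set of genes. At day 0, 50 genes were lower and 0 higher in Quaking KO than in WT cells (edgeR, adjusted p below 0.05), and 39 of the 50 were lower by at least 2-fold; at an unadjusted p below 0.05 there were 826 lower and 111 higher, and DESeq2 called 48 lower and 11 higher. Feature ENSMUSG00000032085.5 measured 41.7 ± 23.4 CPM in WT and 5.70 ± 1.01 in Quaking KO (n = 3; log2 fold change -2.84, SE 0.55, edgeR adjusted p = 0.0471). Feature ENSMUSG00000040152.8 measured 41.8 ± 17.3 CPM in WT and 5.72 ± 1.5 in Quaking KO (log2 fold change -2.81, SE 0.30, edgeR adjusted p = 8.52e-05). Of the 50, 26 were among the 3773 genes that rose at least 2-fold over time in Sam68 KO cells, where 13.8 would be in that list by chance (Fisher's exact test, added after the counts were seen, adjusted p = 0.000772), and 4 were among the 2748 that fell. As a whole the list of rising genes did not pass the camera test (median log2 fold change -0.20, adjusted p = 0.174). It passed without WT day 0 replicate 3 (adjusted p = 0.0228) and under several other settings given with the closing observations. With an estimated correlation it did not pass camera (adjusted p = 0.377). The list's median lay -0.10 from that of all genes, and -0.11 from it under both RLE and upper quartile scaling. Over all genes the median was -0.09 with TMM and -0.00105 with RLE scaling.

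That the day 0 calls all lay in 1 direction depended on the fit. With no filter on low counts 60 were lower and 5 higher. The fit of only the 6 libraries compared called 75 lower and 39 higher, sharing 37 genes with the 50, and neither ENSMUSG00000032085.5 (adjusted p = 0.261) nor ENSMUSG00000040152.8 (adjusted p = 0.0912) passed edgeR's test there. ENSMUSG00000032085.5 was also not past the threshold without Quaking KO day 0 replicates 1, 2 or 3 (edgeR adjusted p = 0.287, 0.161 and 0.239) or WT day 0 replicate 1 (0.0836), with RLE (0.0775) or upper quartile scaling (0.0777), with no filter on low counts (0.183) or on thinning (0.116). The count fell to 23, 30 and 21 without Quaking KO day 0 replicates 1, 2 and 3 and to 24 without WT day 0 replicate 1, and it was 31 under both RLE and upper quartile scaling.

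At day 10 more genes were called between Quaking KO and WT cells. There were 1523 genes higher and 1756 lower (edgeR, adjusted p below 0.05), 23.9% of those tested, with a median absolute log2 fold change of 1.27. The list of 3773 genes that rose in Sam68 KO cells held 621 of the higher and 816 of the lower genes, where 419 and 484 would be there by chance (Fisher's exact test, added after the counts were seen, adjusted p = 2.01e-31 and 7.42e-73). The 2748 that fell held 271 and 234, against 305 and 352 (adjusted p = 0.0307 and 2.29e-14). Neither list moved 1 way against the other genes (median log2 fold change -0.09 and 0.01; camera, adjusted p = 0.440 for each). The rising list lay -0.06 from the median of all genes under TMM, RLE and upper quartile scaling alike, -0.04 without Quaking KO day 10 replicate 2, and -0.03 without WT day 10 replicate 3 or without the 3 dominated libraries. It lay -0.08 from it without Quaking KO day 10 replicate 1, without WT day 10 replicate 1 or on thinning, and -0.07 with no filter on low counts. Of the G1 markers, 10 of 55 were lower (edgeR, adjusted p below 0.05), and the list did not pass the camera test (median log2 fold change -0.19, adjusted p = 0.252).

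The most extreme features at day 10 varied widely between replicates. Feature ENSMUSG00000097603.3 measured 982 ± 953 CPM in Quaking KO and 4.98 ± 4.48 in WT (n = 3; log2 fold change 8.39, SE 1.10, edgeR adjusted p = 0.000112), and ENSMUSG00000085151.7 measured 81.6 ± 108 against 2.01 ± 1.64 (log2 fold change 5.19, SE 1.12, edgeR adjusted p = 0.00460). Feature ENSMUSG00000002012.13 measured 18.9 ± 19.9 in Quaking KO and 6719 ± 11382 in WT (log2 fold change -8.39, SE 2.25, edgeR adjusted p = 0.0168). It rested on WT day 10 replicate 3, without which the log2 fold change was -2.83 (adjusted p = 0.141), and was not past the threshold without Quaking KO day 10 replicate 1 (0.0567) or 3 (0.0646). Feature ENSMUSG00000065770.1 had few counts in Quaking KO, and WT exceeded it by a ratio of 52.8 with a counting interval of 17.8 to 258. The share of higher among called genes was 46.4%, and 54.6% under RLE scaling, so neither direction predominated under both. Fitted on the 6 libraries alone, 1896 genes were called, 1872 of them among the 3279, and neither ENSMUSG00000085151.7 (edgeR adjusted p = 0.170) nor ENSMUSG00000002012.13 (0.199) was past the threshold.

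The comparison of the knockouts at day 10, made within pool MIX_3, gave a similar number. Sam68 KO cells had 1787 genes higher and 1455 lower than Quaking KO cells (edgeR, adjusted p below 0.05), and the split moved from 55.1% higher to 44.5% under RLE scaling. Of the 3279 genes called between Quaking KO and WT at day 10, 2473 (75.4%) were called in the same direction between Quaking KO and Sam68 KO. Independent lists would share 162 of the genes higher in Quaking KO and 229 of the lower, where 1104 and 1369 were shared. Both comparisons use the Quaking KO day 10 libraries. Unchanged groups, all drawn at the Quaking KO day 10 means, were simulated after the agreement was seen. Their mean overlap was 0.1 over 20 simulations (0.3 with the spread of the day's 9 libraries). With no gene changed, few could be called in either comparison. This overlap therefore cannot show how many of the shared calls come from the shared libraries. The covariance of the log2 fold changes was 1.144, against 0.145 simulated (0.194). The 3 Quaking KO day 10 libraries could not be split, so part of the agreement may come from sharing them. Feature ENSMUSG00000069516.8 measured 118 ± 31.9 CPM in Quaking KO and 1.57 ± 1.1 in Sam68 KO (n = 3; log2 fold change of Sam68 KO over Quaking KO -6.92, SE 0.54, edgeR adjusted p = 2.09e-06), and ENSMUSG00000026177.11 measured 14.3 ± 1.00 CPM against 1 count, a ratio of 158 with a counting interval of 27.8 to 6291. Among those higher in Sam68 KO, ENSMUSG00000025352.6 measured 1069 ± 1565 CPM against 9.74 ± 4.67, and ENSMUSG00000037406.7 15.5 ± 17.6 CPM against no count in any Quaking KO library, at least 10.6-fold higher. The latter was not past the threshold without Quaking KO day 10 replicate 2 (edgeR adjusted p = 0.0543) or 3 (0.0587). In the fit of the 6 libraries alone neither ENSMUSG00000025352.6 (0.0911) nor ENSMUSG00000037406.7 (0.359) was. Without the 3 libraries dominated by few features, which leaves 1 Sam68 KO library, the log2 fold change of ENSMUSG00000037406.7 was 4.95. With all libraries it was 9.22. Of the G1 markers 9 were higher and 2 lower in Sam68 KO, and the list did not pass the camera test (adjusted p = 0.193, and 0.469 with an estimated correlation) but did by fry (0.000309).

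At day 0 Sam68 KO cells differed from WT in both directions. There were 85 genes higher and 88 lower (edgeR, adjusted p below 0.05), 48 and 69 of them by at least 2-fold. Feature ENSMUSG00000061928.6 measured 43.5 ± 3.80 CPM in WT and had no count in Sam68 KO, at least 103-fold lower, and ENSMUSG00000047228.9 measured 407 ± 90.7 against 0.504 ± 0.0957 (n = 3; log2 fold change -9.62, SE 0.29, edgeR adjusted p = 1.49e-17). In Quaking KO cells at day 0 these features measured 58.6 ± 7.49 and 211 ± 38.2 CPM. These cells share pool MIX_1 with WT at day 0. In every group of MIX_2 and MIX_3 both features were at most 3.76 CPM. For them pool and loss of Sam68 cannot be told apart. Feature ENSMUSG00000097575.2 measured 64.2 ± 6.87 in Sam68 KO and 1.22 ± 0.765 in WT (log2 fold change 5.84, SE 0.80, edgeR adjusted p = 0.00237), and ENSMUSG00000021381.4 20.7 ± 10.1 against 1.29 ± 0.346 (log2 fold change 4.00, SE 0.73, edgeR adjusted p = 0.00980). The latter was not past the threshold without WT day 0 replicates 1, 2 or 3 (edgeR adjusted p = 0.0645, 0.0606 and 0.0930). Genes that rise with differentiation in Quaking KO cells held 55 of the 85 higher genes, where 23.6 would be there by chance (Fisher's exact test, added after the counts were seen, adjusted p = 8.61e-12), and 19 of the 88 lower ones. Genes that fall held 40 of the lower genes, where 17.4 would be there by chance (adjusted p = 1.46e-07), and 5 of the higher ones. As whole lists, compared with other genes, neither passed the camera test (median log2 fold change 0.07, adjusted p = 0.174, for rising genes and -0.01, adjusted p = 0.178, for falling genes). The former passed without WT day 0 replicate 1 (0.0457) and the latter with no filter on low counts (0.0114). Neither list passed with an estimated correlation (0.377 and 0.481). Without Sam68 KO day 0 replicate 3 their medians were 0.03 and 0.02, against 0.02 over all genes. These groups lay in different pools, and the count was 90 without Sam68 KO day 0 replicate 3, 82 and 94 without WT day 0 replicates 2 and 3, and 296 in the fit of the 6 libraries alone.

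At day 10, 24 genes were called between Sam68 KO and WT cells. There were 10 genes higher and 14 lower (edgeR, adjusted p below 0.05), and 4 of the 173 genes called at day 0 were called again in the same direction. Feature ENSMUSG00000021798.13 measured 71.1 ± 17.2 CPM in Sam68 KO and 20.1 ± 9.27 in WT (n = 3; log2 fold change 1.64, SE 0.26, edgeR adjusted p = 0.00281), and ENSMUSG00000020542.18 23.2 ± 7.30 against 5.81 ± 3.37 (log2 fold change 1.79, SE 0.36, edgeR adjusted p = 0.0429). The latter was not past the threshold without Sam68 KO day 10 replicates 1 or 2 (edgeR adjusted p = 0.223 and 0.323) or WT day 10 replicates 1 or 2 (0.274 and 0.0835). Nor was it in the fit of the 6 libraries alone (0.0655) or on thinning (0.344). The former was not without Sam68 KO day 10 replicate 2 (0.0734) or on thinning (0.0547). Feature ENSMUSG00000097160.2 measured 2.56 ± 1.84 against 22.9 ± 4.18 in WT (log2 fold change -3.62, SE 0.50, edgeR adjusted p = 0.00143), and ENSMUSG00000036896.5 3.23 ± 0.540 against 12.0 ± 4.30 (log2 fold change -2.20, SE 0.30, edgeR adjusted p = 0.00143). ENSMUSG00000036896.5 was not past the threshold in the fit of the 6 libraries alone (0.0536) or on thinning (0.421). All 10 higher genes and 9 of the 14 lower ones were among the 3805 genes that rose with differentiation in Quaking KO cells. By chance 2.78 and 3.89 would be there (Fisher's exact test, added after the counts were seen, adjusted p = 7.22e-06 and 0.00837). Neither the rising nor the falling list passed the camera test (median log2 fold change 0.02 and -0.05, adjusted p = 0.440 and 0.174). The falling list passed with no filter on low counts (0.00138) but not with an estimated correlation (0.481). Without WT day 10 replicate 3 the medians were -0.06 and -0.10, against -0.07 over all genes. Without the 3 libraries dominated by few features they were -0.0097 and -0.0138. The 3 libraries with few features taking most counts all belong to this comparison. Without them, a setting chosen after the data were seen, 1 Sam68 KO library remains, so calls are not given for that setting. The number of genes called was 8 without Sam68 KO day 10 replicate 2, 14, 11 and 58 without WT day 10 replicates 1, 2 and 3, 95 with no filter on low counts and 78 by DESeq2.

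The change with differentiation differed between Quaking KO and WT cells at 1216 genes, 701 with a higher and 515 with a lower change in Quaking KO (edgeR interaction test, adjusted p below 0.05). Of these, 1128 were called between the genotypes at day 10 and not at day 0, 10 at day 0 and not at day 10, and 13 at both. Among 100 splits of the genotype labels within days 6 gave as many genes, all of them among the 14 that kept the real grouping at day 10. Those 14 gave 1039 to 1377 genes whatever the day 0 labels, and the 86 others at most 1. Feature ENSMUSG00000028989.3 measured 284 ± 21.8 CPM in Quaking KO and 17.1 ± 4.72 in WT at day 10, with no count in Quaking KO at day 0, and ENSMUSG00000030074.9 measured 12.8 ± 3.22 against 1.5 ± 0.842 at day 10, likewise with none. The former was not past the threshold on leaving out any 1 library other than WT day 10 replicate 3 (edgeR adjusted p = 0.0504 to 0.152), and the latter without Quaking KO day 0 replicates 1, 2 or 3, Quaking KO day 10 replicate 3, WT day 0 replicate 1 or WT day 10 replicate 2 (0.0601 to 0.128). The replicate block (0.0522) and thinning (1.00) also ended the call of ENSMUSG00000028989.3, and thinning (0.301) and leaving out the 3 dominated libraries (0.0516) that of ENSMUSG00000030074.9. Feature ENSMUSG00000025480.5 had 18.6 ± 3.72 CPM in Quaking KO at day 0 and none at day 10, against 16.0 ± 1.10 and 2.05 ± 0.279 in WT, and ENSMUSG00000078952.9 had 19.4 ± 4.58 and none, against 9.52 ± 1.01 and 0.941 ± 0.891; ENSMUSG00000078952.9 was not past the threshold on thinning (0.144). For Sam68 KO the interaction called 59 genes, 18 higher and 41 lower, of which 50 were called at day 0 and not at day 10, and 7 of 100 splits gave as many, 4 of them among the 82 that kept neither day's real grouping. Among the 59 ENSMUSG00000047228.9 had a log2 interaction of 8.25 (SE 0.73, edgeR adjusted p = 4.87e-07), while ENSMUSG00000021381.4 had -6.09 (SE 1.19, edgeR adjusted p = 0.0374) and ENSMUSG00000056888.11 -3.43 (SE 0.61, edgeR adjusted p = 0.00772). ENSMUSG00000021381.4 measured 20.7 CPM in Sam68 KO at day 0 and 12.3 ± 15.8 in WT at day 10, both in MIX_2. It measured at most 1.57 in the other groups. ENSMUSG00000056888.11 measured 10.8 and 14.8 CPM in these MIX_2 groups, 1.62 in WT at day 0 and 9.47 in Sam68 KO at day 10. Both MIX_2 groups lie on the same side of this interaction, so it does not separate pool from loss of Sam68. ENSMUSG00000047228.9 measured 407 CPM at day 0 and 3.76 at day 10 in WT, and 0.504 and 0.803 in Sam68 KO. It was thus low in both lines at day 10, and high only in the groups of MIX_1. Feature ENSMUSG00000077704.1 had no count in Sam68 KO at day 0 and 7.13 ± 2.52 CPM at day 10, against 2.28 ± 0.702 and 11.2 ± 5.75 in WT (edgeR adjusted p = 0.0484). It was not past the threshold on leaving out any 1 library other than WT day 10 replicates 2 and 3 (0.0538 to 0.187), nor was ENSMUSG00000021381.4 on leaving out any other than Sam68 KO day 0 replicate 1 and WT day 10 replicates 2 and 3 (0.0594 to 0.121), nor ENSMUSG00000056888.11 without Sam68 KO day 10 replicate 2 (0.0666). On thinning the calls of ENSMUSG00000047228.9 (log2 interaction 5.26, adjusted p = 1.00) and ENSMUSG00000056888.11 (0.476) were lost, in the fit of only the compared groups that of ENSMUSG00000021381.4 (0.0693), and under upper quartile scaling (0.0516) that of ENSMUSG00000077704.1. The Sam68 KO count was 25 and 29 without Sam68 KO day 0 replicates 2 and 3, 12 and 26 without Sam68 KO day 10 replicates 2 and 3, 29 and 28 without WT day 0 replicates 2 and 3, and 23, 39 and 90 without WT day 10 replicates 1, 2 and 3.

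Few genes were called against WT in both knockouts. At day 0, 5 genes were lower in both and 5 were called in opposite directions, and 0.321 lower in both would come from independent lists. At day 10, 2 were higher and 5 lower in both, against 1.11 and 1.79, and 7 were opposite. The number of opposite calls from independent lists was not computed. At day 10 only 24 genes were called for Sam68 KO, so the overlap could not be large. Of all genes tested, 23.9% were called for Quaking KO there. In the comparisons simulated 26% to 34% of 2-fold changes were recovered, so shared differences may have been missed. Unchanged groups, WT included, were simulated at the WT means of each day. Their mean overlap was 0.05 at day 0 and 0.2 at day 10 over 20 simulations. With the spread of that day's 9 libraries it was 0.1 on each day. With no gene changed few could be called, so these overlaps do not measure what shared WT libraries add to the observed ones. The observed overlap was 10 and 23 with no filter on low counts, and 30 at day 10 by DESeq2. Across genes the log2 fold changes of the knockouts correlated with r = 0.105 at day 0 and 0.232 at day 10, below the means of 0.381 and 0.487 in the simulations. The covariance was 0.0435 at day 0, against 0.109 simulated, and 0.165 at day 10, against 0.133; with the spread of that day's 9 libraries in the simulation it was 0.0870 and 0.180. The observed covariance was below the simulated one at day 0, and at day 10 the sign of the difference turned with the spread used. With 3 WT libraries the controls could not be split, so part of any overlap may come from sharing them.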

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

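Of the tests in this part, the one on the spread shared with the day 10 libraries was chosen only after its result was seen, and so were the split of the Sam68 KO genes by level, the separation of splits by the groupings they keep, the list of rising genes and the fit without the 3 libraries dominated by 10 features. The first results below are listed because the effect of a knockout differed between day 0 and day 10 by an interaction test. No group had 4 or more libraries, so no single library was tested for standing apart.

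The effect of Quaking loss differed between the days at 1216 genes. Among 100 splits of the genotype labels within days, the real one included, 6 gave as many genes, with 1377 in the highest other. All 6 were among the 14 splits that kept the real grouping at day 10, which gave 1039 to 1377 genes, and the 86 others gave at most 1. Splits that keep this grouping carry the day 10 difference whatever the day 0 labels, so the count of 6 does not measure chance. The Sam68 KO effect differed at 59 genes, and 7 of 100 splits gave as many, with 249 in the highest other. Both MIX_2 groups lie on the same side of this interaction, so it does not separate pool from loss of Sam68. Of the 7, 3 kept the real grouping at day 0, the real split among them, and likewise do not measure chance. The 82 splits that kept neither day's grouping gave up to 117 genes, and 4 of them as many as the real split. With the real split that is 5 of 83, a share of 0.0602, so chance is not excluded at 0.05. For Quaking KO the 73 splits that kept neither gave at most 1. Such splits mix both genotypes within a group, and at day 10 Quaking KO and WT differed at 3279 genes. This adds to the spread and lowers the count. Splits that break a grouping, those of Sam68 KO included, therefore do not measure chance for the interaction alone.

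The wide difference between Quaking KO and WT at day 10 lay across pools MIX_3 and MIX_2. A pool effect would move the same genes in Sam68 KO, which shares MIX_3, but their median signed shift in Sam68 KO vs WT was 7.17% of that in Quaking KO, and 4.14% to 10.7% on leaving out any day 10 library. One WT library with few features taking most counts does not account for it, since 2953 of the 3279 genes (90.1%) were called in the same direction without it. Thinning to 1 total gave 2143 genes at day 10 and 22 at day 0, a ratio of 97.4, so the excess remained. Lower depth at day 10 would remove calls there, so thinning could not have pointed to it as the cause. A response to the loss of Quaking during differentiation is a candidate explanation, as a hypothesis that independent clones or restored Quaking would test. Clonal differences stay open, as does the speed of differentiation as a part of it. Genes that rise with differentiation (621 higher, 816 lower) did not pass the test of a shift against other genes (camera, adjusted p = 0.440). They passed by fry, which does not compare a list with other genes (median log2 fold change -0.09, adjusted p = 0.0202). In 10 splits of the 6 libraries the highest other gave 3 genes against 3279, and 10 are too few for a share under 0.05.

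The genes called in Quaking KO at day 0 were all lower. The greater depth of the WT libraries is argued against, since 100% of the 22 genes called after thinning were lower. Under RLE and upper quartile scaling 100% of the calls were lower, so scaling does not account for all of it. Only 31 of the 50 stayed past the threshold under each. The median log2 fold change over all genes moved from -0.09 to -0.00105 and -0.00756. Scaling could therefore account for part of the pattern. The spread borrowed from the day 10 libraries could account for part of it, since in the fit of the 6 libraries alone 65.8% of 114 calls were lower. It is not the only such setting, since DESeq2 (11 higher, 48 lower) and no filter on low counts (5 higher, 60 lower) also called higher genes with all 18 libraries in the fit. The 10 splits gave 50 for the real grouping and 0 for the highest other, too few for a share under 0.05.

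More genes were called for Sam68 KO at day 0 (173) than at day 10 (24). If no pool effect is at work, lower power is argued against as the reason that most of these 173 genes were not called at day 10. Their median signed shift there was 1.52% of that at day 0 (-3.88% to 2.70% on leaving out a library). It was -6.86% for the 127 with a mean of at least 10 CPM at day 10. For the 46 below that level it was 19.8%, and 73.9% of them kept their sign. MIX_2 enters the comparisons of day 0 and day 10 with opposite signs. A MIX_2 effect could therefore cancel a shift kept at day 10, so these values do not settle the matter. Whether changes of other genes were missed at day 10 was not tested, so lower power stays open for those too. The day 10 count was 8 to 58 on leaving out a library and 78 by DESeq2. The pool stays open: between the knockouts at day 10, which share a pool, the shift was 4.14% of that at day 0 and 52.6% of the genes moved the same way, as a pool effect of MIX_2 against MIX_1 predicts. An effect of Sam68 loss limited to day 0 predicts the same, and the 2 cannot be told apart because pool and genotype are confounded there. Splits gave 173 for the real grouping and 0 for the highest other at day 0, again with 10 splits only.

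For Sam68 KO vs WT at day 10, 2 of the 10 splits gave at least 24 genes, and the highest other gave 436. That split set WT replicate 3 and Sam68 KO replicates 2 and 3, the libraries with 60.2% to 70.4% of their counts in 10 features, against the rest, which points to a structure of these libraries other than genotype; 10 splits are too few for a share under 0.05. The fit without these libraries keeps 1 Sam68 KO library, assumed to vary like the other groups, so its count of calls is not given. For the time courses the real values were 8905 (WT), 8777 (Quaking KO) and 8948 (Sam68 KO), and the highest other was 0 in each. For Sam68 KO vs Quaking KO at day 10 they were 3242 and 1. In each of these 4 comparisons 10 splits are too few for a share under 0.05.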

How the results depend on the processing

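Leaving out the 3 libraries dominated by few features and the tests of the gene lists were chosen only after the data were seen. Counts that moved by over 1.5 times are given here by setting; the cause was not tested unless stated. RLE and upper quartile scaling each gave 31 genes for Quaking KO vs WT at day 0. With no low-count filter there were 268 for Sam68 KO vs WT at day 0, 95 at day 10 and 129 for its interaction, and overlaps of the knockouts of 10 at day 0 and 23 at day 10. DESeq2 gave 78 for Sam68 KO vs WT at day 10, 130 for its interaction and an overlap of 30 at day 10. Fitting only the compared groups gave 114 (Quaking KO) and 296 (Sam68 KO) at day 0, 1896 for Quaking KO at day 10 and 35 for the Sam68 KO interaction. Thinning to the smallest library, which removes counts, gave 22 and 84 at day 0 and 2143 and 12 at day 10 for Quaking KO and Sam68 KO, 605 and 27 for their interactions and 1996 for Sam68 KO vs Quaking KO. Leaving out the 3 libraries dominated by few features keeps 1 Sam68 KO library at day 10, so counts that use this group are not given.

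With pool as a block in the additive model, 1201 genes were called for Sam68 KO (1 effect for both days) and 5570 for day. Its construction takes the Quaking KO effect to be equal on both days, whereas the interaction called 1216 genes, so it is not used as a correction for pool. In it ENSMUSG00000021381.4 (-0.13), ENSMUSG00000061928.6 (0.42) and ENSMUSG00000047228.9 (0.87) reversed their day 0 Sam68 KO log2 fold change, ENSMUSG00000020542.18 (-2.08) and ENSMUSG00000097160.2 (0.64) their day 10 one, and ENSMUSG00000061928.6 (2.57) its change over time in Quaking KO; none was past the threshold there.

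Leaving out 1 library at a time gave, for vs WT, 21 to 45 (Quaking KO, day 0), 82 to 210 (Sam68 KO, day 0), 2378 to 3284 (Quaking KO, day 10) and 8 to 58 (Sam68 KO, day 10). It gave 8002 to 8839 (WT), 8039 to 8570 (Quaking KO) and 8160 to 8456 (Sam68 KO) for the time courses, 908 to 1246 and 12 to 90 for the Quaking KO and Sam68 KO interactions, and 2304 to 3117 for Sam68 KO vs Quaking KO. Of 588 values of named features under alternatives, 493 stayed past the threshold in the same direction, 89 did not and 6 reversed. Of the values of gene lists, 199 kept their side of the threshold, 44 newly passed it and 5 no longer did.

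Replicate numbers did not pair the libraries: in 0 of 15 pairs of groups did every same-numbered correlation exceed 0.1 (range -0.187 to 0.442). The replicate block gave 55, 164, 3068 and 24 genes for Quaking KO and Sam68 KO at day 0 and then at day 10, 8703, 8668 and 8847 for the time courses, 1145 and 55 for the interactions and 3115 for Sam68 KO vs Quaking KO. The protein-coding-only alternative and the symbol-based lists were not run. In the 3 comparisons simulated (Quaking KO vs WT on both days and Sam68 KO vs WT at day 10) 26% to 34% of 2-fold changes were recovered.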

Other observations

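The gene lists and their tests were chosen only after the data had been seen, and Fisher's exact tests after the camera test of the same lists had not passed. Genes called in the knockouts fell unevenly over the lists of genes that change with differentiation. At day 0 the 50 genes lower in Quaking KO held 26 rising genes (odds ratio 2.86, 95% interval 1.58 to 5.22; Fisher's exact test, adjusted p = 0.000772 over 16 tests). For Sam68 KO the higher genes at day 0 held more rising genes (55 of 85, odds ratio 4.82; adjusted p = 8.61e-12) and the lower ones more falling genes (40 of 88, odds ratio 3.41; adjusted p = 1.46e-07). At day 10 both the higher and the lower genes of Quaking KO held more rising genes (621, odds ratio 1.97, and 816, odds ratio 2.64). Genes are not independent in these tests, so the p-values are too small. The tests also take every gene as equally likely to be called, and the lists were not matched for level. In the line that defined them, rising genes had more counts at day 10 and falling genes fewer. Level may therefore account for part of the unevenness, which was not tested. The Sam68 KO result also shares pool MIX_1 at its baseline with the time course that defined the lists.

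Of the 50 genes lower in Quaking KO at day 0, 26 were also lower and 8 higher than WT at day 10. By fry, which asks whether a list moves 1 way and does not compare it with other genes, the rising list passed in Quaking KO at day 0 (median log2 fold change -0.20, against -0.09 over all genes; adjusted p = 0.000653) and at day 10 (-0.09, against -0.03, with 621 members called higher and 816 lower; adjusted p = 0.0202). At day 10 camera did not pass for this list (adjusted p = 0.440, and 0.481 with an estimated correlation). Its median less that of all genes was -0.06 under TMM, RLE and upper quartile scaling, -0.04 without Quaking KO day 10 replicate 2 and -0.03 without WT day 10 replicate 3 or the 3 dominated libraries. This difference was -0.08 without Quaking KO day 10 replicate 1, without WT day 10 replicate 1 or on thinning, and -0.07 with no filter. By camera the day 0 list did not pass with TMM scaling (adjusted p = 0.174), nor with the replicate block (0.156), an estimated correlation (0.377) or without Quaking KO day 0 replicates 1, 2 or 3 or WT day 0 replicates 1 or 2 (0.0984 to 0.445). It passed with RLE (0.00987) or upper quartile scaling (0.0120), no filter on low counts (0.0114), the 6 libraries alone (0.00950), thinning (0.0354) and without WT day 0 replicate 3 (0.0228), so the call depends on the setting. Its median less that of all genes was -0.10 with TMM, -0.11 with RLE, upper quartile scaling and the 6 libraries alone, -0.14 with no filter, -0.08 on thinning, -0.13 without WT day 0 replicate 3 and -0.07 without WT day 0 replicate 1. The falling list likewise did not pass at day 0 (0.174), nor with the replicate block (0.156), no filter on low counts (0.0945) or an estimated correlation (0.481). Without Quaking KO day 0 replicates 1, 2 or 3 or WT day 0 replicates 1 or 2 it did not pass either (0.0728 to 0.328). It passed with RLE (0.00987) or upper quartile scaling (0.0120), the 6 libraries alone (0.00748), thinning (0.0354) and without WT day 0 replicate 3 (0.0228). The median of the falling list less that of all genes was 0.05 with TMM, RLE, upper quartile scaling and the 6 libraries alone. It was 0.04 on thinning and 0.06 without WT day 0 replicate 3. In the comparisons of a knockout with WT no cell-cycle list passed camera, with the lowest adjusted p, 0.252, for the G1 markers in Quaking KO at day 10 (0.469 with an estimated correlation). By fry this list passed there (adjusted p = 0.000347; median -0.19, against -0.03 over all genes). At day 0 it gave 0.0197, but there the median of the list (-0.09) was close to that of all genes (-0.09), which was 0.00 under RLE scaling, so it does not set these markers apart.

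ENSMUSG00000061928.6 and ENSMUSG00000047228.9 measured 43.5 and 407 CPM in WT stem cells and 0 and 0.504 CPM in Sam68 KO stem cells, with 58.6 and 211 CPM in Quaking KO stem cells. At day 10 ENSMUSG00000061928.6 had 0.0738 CPM in WT and ENSMUSG00000047228.9 had 3.76 CPM. In both knockouts at day 10 these features had at most 0.803 CPM. They were thus high only in the groups of MIX_1, WT and Quaking KO at day 0. Pool and loss of Sam68 cannot be told apart for them. The 46 genes called at day 0 with a mean under 10 CPM at day 10 had a median signed shift of 0.63 at day 10 against 3.19 at day 0, 19.8%. No explanation was tested for these features alone.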
